A study of Rattus norvegicus with 10 samples.

How the data were processed

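RNA was measured in 10 libraries of rat TDSCs on day 3 of osteogenic induction, 5 control and 5 with 50 µM farnesol, grouped by the sample labels. Per the labels, total RNA was taken with Trizol and libraries were made with the NEBNext Ultra II RNA kit; whether counting used strand is not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart. The submitters' processing notes name HISAT2 2.0.5, HTSeq 0.9.1, DESeq, StringTie and build rn7, with no role given to each. The authors deposited 1 table with read counts per gene and library, and with FPKM values beside them, per the file headers. The deposited FPKM values equal the count divided by 1 length per gene and the total of the column, within a relative spread of 2.56e-05 over libraries, so gene length was taken from that ratio. Counting reads over annotated genes and dividing by length leaves out reads that fall in more than 1 gene, if such reads were dropped, and this could lower genes with close copies.

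The table had 23052 rows, of which 1 repeated another with equal values and was removed. Of the 23051 genes kept, 2744 had no symbol and were named by their Ensembl identifier, since none matched in the RefSeq gene table, and 5536 were at 0 in every library. No column of values lacked a sample. Depth was 41.8 to 47.1 M counts per library, and a count of 0 allows up to 3 counts, or 0.064 to 0.072 CPM depending on the library; these limits cover counting error only.

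Counts were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM normalization, robust glmQLFit and glmQLFTest, group as the only term), with Benjamini-Hochberg adjustment over 12893 genes at 0.05. The SE of a log2 fold change is its size divided by the square root of the F statistic. CPM values use TMM-scaled library sizes, and log2 CPM a prior count of 2. Folds are 2 to the power of the fitted log2 fold change, and a fold lower is its inverse. The common biological coefficient of variation was 0.125.

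Before the data were examined, 33 gene lists were fixed for the lineages of tendon, bone, cartilage and fat, sterol and lipid metabolism, oxidant defence, MAPK and other signalling, stress, other cell types and RNA quality. Lists with at least 5 tested members, 30 in all, were tested with camera of limma 3.58.1 (preset correlation 0.01, 2-sided, adjusted over the lists). Beside it stand camera with an estimated correlation and fry. With an estimated correlation only the sterol and YAP lists kept an adjusted p under 0.05, of the 14 called. Without a covariate, counts of members of the fixed lists adjusted over the list alone equal those over all genes except where both are given. Some fixed members were not analysed here, and a few genes belong to more than 1 list, such as Egr1 and Tgfb2. KEGG pathway names in the table gave 330 pathways of 10 to 300 tested genes.

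Genes were named by a rule fixed at the same time as the lists: Gstp1 and 21 further fixed genes, the 10 largest rises and the 10 largest falls at an adjusted p under 0.05 with no overlap of the groups and at least 5 CPM in the higher group, and up to 4 members with the smallest p of each list; members that did not pass may be named with values only, as Pdgfrb and Cspg4 are. Of these, Sp7, Bglap, Tnmd and Mapk3 were not tested because their counts were low or 0. Some genes that the rule names are not reported here.

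The library axis is the first principal component of log2 CPM after each group's mean is taken off, and a library's score is its projection. The length slope is the slope of a library's log2 ratio to the mean of all libraries on log2 gene length. Both were used as covariates after seeing the data, as was a smooth length trend (5 degrees of freedom) removed from each library. Farnesol and the axis run together, so a covariate can also take up part of a real effect. Other alternatives were each library left out, the replicate number as a block, other size factors, filters, thresholds and tests, limma-trend on FPKM, limma-voom with quality weights and DESeq2 1.42.0.

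The steps were tested on simulated counts drawn for 12893 genes with the means, dispersions and library sizes of farnesol against control. Of 50 genes each seeded at 1.25, 1.5, 2 and 4-fold, 14, 42, 45 and 50 were recovered, and 5.62% of the calls were false. With a simulated library axis and the axis as a covariate, 6, 26, 40 and 50 were recovered; which of the 2 lowers the number was not tested. With 1 list shifted, that list and 1 other were called. With a simulated library axis that runs with the groups and no other effect, 1757 genes were called without a covariate, 0 with the axis and 1 with the length slope as a covariate. The dispersions drawn already held the real spread along the axis, so 1757 may be too low to set beside the real count. Between replicate libraries, the chi-square of counts per gene was 3.96 to 112 over 20 pairs, above sampling noise in each, so no library was taken for a repeat deposit of another; separate libraries of 1 RNA are not excluded by this.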

Results

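Gene expression was measured by bulk RNA sequencing in rat tendon-derived stem cells (TDSCs), progenitor cells of tendon that can be steered towards bone. All cultures were under osteogenic induction and were taken on day 3. The 10 libraries form 2 groups of 5: induction alone (control) and induction with 50 µM farnesol, an isoprenoid alcohol made from an intermediate of the mevalonate pathway. The titles call the controls untreated, whereas their library names point to a vehicle, so the solvent of the controls is open. The table held 41.8 to 47.1 M (mega) counts per library, on average 44.8 M ± 1.94 (SD, n = 5) in control and 44.82 M ± 1.72 (SD, n = 5) in farnesol. The labels number biological replicates but do not say whether these came from separate animals or cultures, so p-values measure the spread between these samples, which may be technical. The comparison asks which genes farnesol changes during induction, and the series title names Gstp1 and the mitogen-activated protein kinases (MAPKs).

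With farnesol, 23 of 26 genes of sterol and mevalonate synthesis rose (camera adjusted p = 5.11e-11), and 10 of 14 markers of contractile and mural cells fell (camera adjusted p = 8.77e-06, and adjusted p = 0.136 with an estimated correlation). Acat2, which makes acetoacetyl-CoA (chromosome 1, 47695788 to 47752821, build rn7 per the submitters' processing notes), rose from 47.7 ± 2.18 to 103 ± 1.78 CPM (counts scaled to library size, mean ± SD, n = 5), or 2.17-fold. Myh11, the smooth muscle myosin heavy chain (chromosome 10, 743685 to 838459), fell from 857 ± 38.2 to 292 ± 10.4 CPM, and Postn, a matrix protein of bone and tendon, from 283 ± 15.9 to 94.5 ± 12.9 CPM. Gstp1, a glutathione S-transferase, rose from 140 ± 18 to 314 ± 57.3 CPM. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 7671 of 12893 tested genes changed at an adjusted p under 0.05, of which 3796 rose and 3875 fell, and 136 rose and 619 fell by at least 1 on the log2 scale.

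Libraries of one group also differed among themselves, and 1 direction, here called the library axis, held 36.8% of the variance within groups. On average farnesol libraries lay further along it (mean score 21.6, against -21.6 in control), although control 3 (4.06) lay beyond farnesol 3 (-0.074). Its scores ran against the length slope (correlation over libraries -0.982), so as covariates they are not separate checks. With farnesol shorter genes tended to rise and longer genes to fall. The median log2 fold change was 0.32 in genes up to 1346 bp and -0.31 in genes of at least 6700 bp. The count of changed genes was 2656 with each library's score on this axis as a covariate and 976 with each library's length slope as a covariate, both alternatives chosen after seeing the data, and 751 genes (296 that rose and 455 that fell) changed the same way in all 3 fits. With a smooth length trend removed from each library, also chosen after seeing the data, the count was 7300. Of these, 5964 also changed the same way in the fit without a covariate, and 26 the other way. Values below come from the fit without a covariate, and a gene or list whose call ended with a covariate is named as such.

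Gstp1 lies on chromosome 1 from 201321672 to 201340226 on the minus strand, in the same build. Its level was 119.5, 136, 166.2, 147.5 and 128.8 CPM in control replicates 1 to 5 and 305.3, 304.5, 265.7, 282.8 and 412.3 CPM in farnesol replicates 1 to 5. It was higher in each farnesol library than in every control library, by a log2 fold change of 1.17 (SE 0.12, adjusted p = 1e-05, edgeR). The log2 fold change was 0.71 with the axis as a covariate and 0.56 with the length slope, both past the threshold. Of 28 tested genes of the glutathione list, 20 rose (21 adjusted over the list alone), 1 fell and 7 did not pass (camera adjusted p = 1.97e-05, and adjusted p = 0.208 with an estimated correlation). Gsta1, which conjugates glutathione to electrophiles, rose 1.77-fold, Gsta4 1.62-fold and Mgst1, a microsomal enzyme, 1.64-fold. The number that rose was 11 with the axis and 5 with the length slope as a covariate (13 and 8 adjusted over the list alone), the latter leaving out Mgst1. The cytosolic transferases include close copies whose reads the counting could have split.

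**Figure D1:**
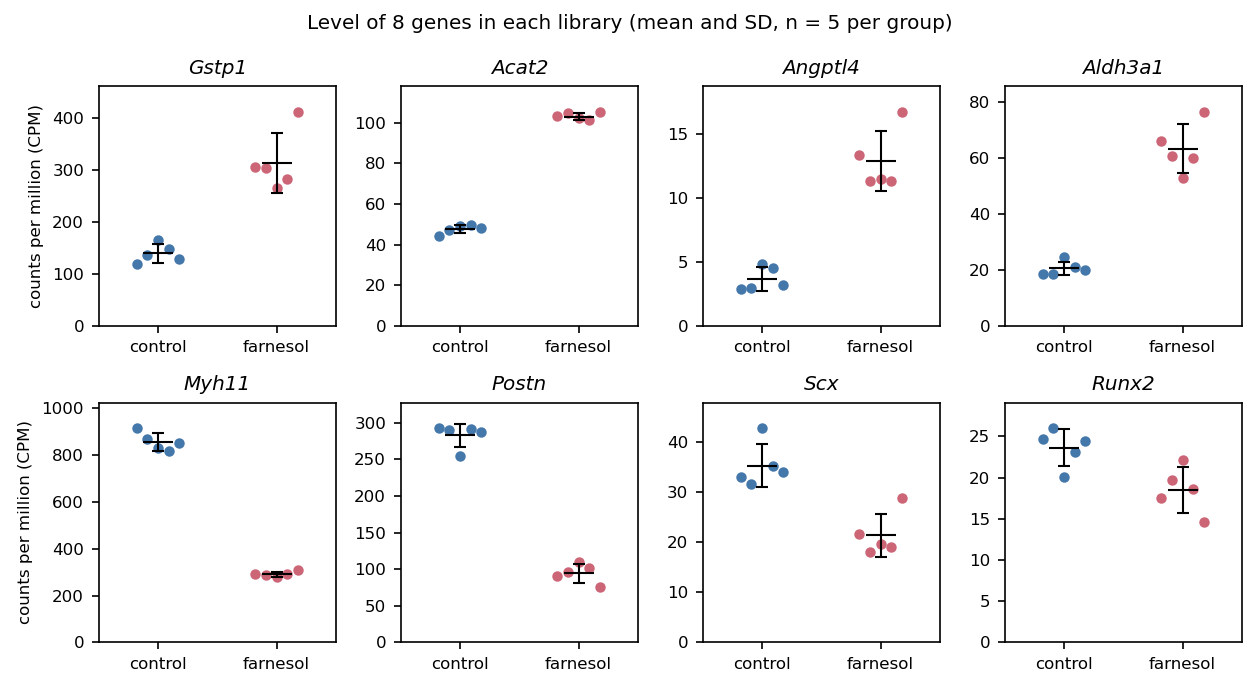
Level of 8 genes in CPM (vertical axes, each from 0) in the 5 control and 5 farnesol libraries; points are libraries, in the order of replicate 1 to 5, and bars are the mean ± SD of the group. Gstp1, Acat2, Angptl4 and Aldh3a1 lie higher in every farnesol library, Myh11, Postn and Scx lie lower, and Runx2 overlaps between the groups.

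Sterol and mevalonate synthesis moved almost as a whole. Of its 26 genes, 23 rose, 1 fell and 2 did not pass (camera adjusted p = 5.11e-11, and adjusted p = 0.00144 with an estimated correlation). Beside Acat2, Cyp51, a lanosterol demethylase, rose 1.87-fold and Fdft1, the squalene synthase, 1.84-fold. Insig1, which holds the sterol sensor in the endoplasmic reticulum, rose from 73.5 ± 4.31 to 151 ± 12.5 CPM. Hmgcs1 rose 1.51-fold. The median log2 fold change of the list was 0.70, and 0.72 and 0.73 with the covariates. Mvd and Dhcr7, enzymes of the same pathway, were among the 10 largest rises, at 2.55-fold and 2.52-fold. In fatty acid synthesis 9 of 15 genes rose and 1 fell (camera adjusted p = 0.0014, and adjusted p = 0.0731 with an estimated correlation). Scd2, a desaturase, rose 1.86-fold, Fads2 1.81-fold, Acss2 1.76-fold and Fads1 1.68-fold.

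Among PPAR targets and fatty acid oxidation 15 of 24 genes rose and 1 fell (camera adjusted p = 0.00687, and adjusted p = 0.184 with an estimated correlation), and 6 and 4 rose with the axis and the length slope as covariates. Angptl4, a secreted inhibitor of lipoprotein lipase, had the largest rise of the eligible genes, from 3.68 ± 0.922 to 12.9 ± 2.34 CPM (3.5-fold). Plin2, which coats lipid droplets, rose 1.62-fold and Hadha, of mitochondrial beta-oxidation, 1.42-fold; Acaa2 rose 1.44-fold, a call that ended with the length slope. Of 12 adipocyte genes 5 rose (6 adjusted over the list alone) and 2 fell (camera adjusted p = 0.107), among them Fabp4 at 1.95-fold, Plin4 at 1.75-fold and Dgat2 at 1.6-fold. Liver X and farnesoid X receptor targets went both ways, with 3 of 11 higher (4 adjusted over the list alone) and 3 lower (camera adjusted p = 0.767, mean and median of unlike sign). Lpcat3 rose 1.41-fold, and Abca1, a cholesterol exporter, fell by 0.48 on the log2 scale, which ended with either covariate.

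Oxidant defence and stress genes were mostly higher. Of 24 NRF2 targets 14 rose and 4 fell (camera adjusted p = 0.0202, and adjusted p = 0.184 with an estimated correlation). With the axis and the length slope as covariates 10 and 7 rose, and the median log2 fold change went from 0.40 to 0.14 and 0.12. Tkt rose 1.9-fold, Fth1, the ferritin heavy chain, 1.56-fold, and Hmox1 1.47-fold. Aldh3a1, an aldehyde dehydrogenase, and Akr1b8, an aldo-keto reductase, rose 3.08-fold and 2.51-fold. Of 28 genes of the unfolded protein response and ATF4 16 rose and 5 fell (camera adjusted p = 0.0283, and adjusted p = 0.184 with an estimated correlation), a call that ended with the length slope (adjusted p = 0.0984). Ddit4, an inhibitor of mTOR signalling, rose 2.08-fold, while Vldlr was 1.7-fold lower. Ddit3 rose 1.56-fold and Shmt2 1.37-fold, and both calls ended with the length slope.

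Of 14 tested markers of smooth muscle, pericytes and myofibroblasts 10 fell, none rose and 4 did not pass (camera adjusted p = 8.77e-06, and adjusted p = 0.136 with an estimated correlation, against 0.016 with the axis and 0.0205 with the length slope as covariates). Mylk, the myosin light chain kinase, was 3.52-fold lower, Mcam 2.38-fold and Cnn1, calponin, 2.02-fold. Acta2, smooth muscle actin, chosen after its values were seen, was 6080 ± 365 CPM in control and 3810 ± 271 CPM in farnesol. Pdgfrb, at 782 ± 19.5 and 750 ± 44.5 CPM, and Cspg4, at 186 ± 11.1 and 176 ± 26.3 CPM, did not pass, although Cspg4 did without farnesol replicate 5 (log2 fold change -0.17, adjusted p = 0.0104), with the axis (-0.37, adjusted p = 9.91e-05) and with the length slope (-0.41, adjusted p = 0.00421), and Pdgfrb with the axis (-0.16, adjusted p = 0.00814). With a length trend removed from each library Pdgfrb was higher instead (0.20, adjusted p = 0.0294). With the axis as a covariate 12 of the markers fell and with the length slope 11 (13 in either adjusted over the list alone). Of 14 YAP targets, which respond to tension, 13 fell and 1 did not pass (camera adjusted p = 3.9e-06, and adjusted p = 0.0427 with an estimated correlation). F3 was 2.12-fold lower, Lats2 1.88-fold, Tgfb2 1.71-fold and Ankrd1 1.68-fold.

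Of 21 tested tendon genes 3 rose, 11 fell and 7 did not pass (camera adjusted p = 0.0202, and adjusted p = 0.114 with an estimated correlation). The call ended with a length trend removed from each library (median log2 fold change -0.05 against -0.20, adjusted p = 0.0909). Tnc fell from 3200 ± 122 to 1320 ± 89 CPM. Scx, a transcription factor of tendon, fell from 35.3 ± 4.35 to 21.4 ± 4.34 CPM, with a log2 fold change of -0.72 and, with the covariates, of -1.18 and -1.29. Egr1 was 1.52-fold lower and Dcn 1.52-fold lower, the latter not called with the length slope (adjusted p = 0.0527). Col12a1, 1.84-fold lower, and Mkx, with a log2 fold change of -0.46, were not called with either covariate. Tnmd had 0 or 1 counts per library and was not tested.

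Bone genes moved apart from each other. Of 25 tested 5 rose, 12 fell and 8 did not pass, and the list was not called (camera adjusted p = 0.0847), whereas it was with the axis (adjusted p = 0.00517, and adjusted p = 0.0655 with an estimated correlation) and the length slope (adjusted p = 0.00155, and adjusted p = 0.0411 with an estimated correlation) as covariates, without control replicate 5 (adjusted p = 0.0474) and without farnesol replicate 5 (adjusted p = 0.039). Tnfrsf11b, the decoy receptor of RANKL, fell from 659 ± 67.7 to 244 ± 46.7 CPM, Omd was 1.71-fold and Enpp1, which makes pyrophosphate, 1.61-fold lower. Ibsp fell from 6.6 ± 0.358 to 2.95 ± 0.316 CPM. Runx2, which drives the osteoblast fate, was 23.6 ± 2.26 CPM in control and 18.5 ± 2.77 CPM in farnesol, with overlapping groups. Its log2 fold change was -0.35 (SE 0.11, adjusted p = 0.0117, edgeR), and 0.02 and 0.12 with the covariates, where it was no longer called. Alpl, at 2.61 ± 0.385 and 1.93 ± 0.216 CPM, had a log2 fold change of -0.43 (SE 0.15, adjusted p = 0.0226, edgeR). The call was lost without control replicates 3 or 4 or farnesol replicates 1 or 2 (highest adjusted p = 0.0632). Its log2 fold change was -0.69 with the axis, where it stayed called (adjusted p = 0.0439), and -0.81 with the length slope. There the SE was 0.29 and the call was lost (adjusted p = 0.099). Spp1 rose by 0.16 on the log2 scale with overlapping groups. It stayed called with the axis (0.28, adjusted p = 1.49e-07) and with the length slope (0.30, adjusted p = 0.000389). Its call ended with a length trend removed from each library (-0.01, adjusted p = 0.923). Col1a1 did not pass (15000 ± 472 and 15700 ± 687 CPM), although it did with that trend removed (0.34, adjusted p = 0.0017). Sp7 had 0 to 8 and Bglap 0 to 11 counts per library, too few to test.

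Of 13 cartilage genes 2 rose (1 adjusted over the list alone) and 2 fell (camera adjusted p = 0.996, with a median above and a test below 0). Acan, the aggrecan core protein, fell from 18.3 ± 1.15 to 4.47 ± 0.992 CPM; Col11a1 was 1.36-fold lower and Sox9 1.45-fold higher, and both calls ended with either covariate.

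MAPK genes went both ways. Of 36 cascade components 11 rose (12 adjusted over the list alone), 14 fell and 11 did not pass (camera adjusted p = 0.873, median above and test below 0). Mapk14, which encodes p38 alpha, was 81.3 ± 2.71 and 82 ± 2.64 CPM and did not pass. Mapk8, which encodes JNK1, fell from 22.7 ± 3.48 to 16.8 ± 1.67 CPM and Map3k5 by 0.36 on the log2 scale, and both calls ended with either covariate. The Map3k5 call was also lost without control replicates 1, 2 or 4 or farnesol replicate 1 (highest adjusted p = 0.0669). Map3k20 was 1.62-fold lower and passed in all 3 fits. Rps6ka3 and Nras were 1.63-fold and 1.43-fold lower and Mapkapk3 1.33-fold higher, calls that ended with the length slope. Mapk3, which encodes ERK1, was listed at 0 in all 10 libraries; whether the counting left out its reads is not given in the sources used here, so its level is unknown. Among genes that MAPK signalling switches on, 4 of 27 rose and 14 fell (camera adjusted p = 0.0202, and adjusted p = 0.114 with an estimated correlation). Dusp8 was 3.6-fold lower (1.84 ± 0.457 and 0.509 ± 0.148 CPM) and Fosb 2.22-fold lower (4.07 ± 0.77 and 1.83 ± 0.284 CPM). Fos was 2.15-fold lower (2.99 ± 0.249 and 1.39 ± 0.311 CPM) and was not called with the length slope (adjusted p = 0.165). These 3 genes were at low levels. Ccnd1 rose 1.6-fold (390 ± 11.6 and 625 ± 81.1 CPM), and Dusp6 did not pass (29.9 ± 1.69 and 26.6 ± 3.5 CPM).

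Of 29 BMP and TGF-beta genes 7 rose and 16 fell (8 and 17 adjusted over the list alone; camera adjusted p = 0.0326, and adjusted p = 0.184 with an estimated correlation). Grem1, a BMP antagonist, fell from 2210 ± 122 to 809 ± 76.2 CPM, Id4 was 2.05-fold and Tgfb3 1.43-fold lower. Of 20 Wnt genes 3 rose and 11 fell (camera adjusted p = 0.124). Nkd2 was 2.12-fold, Axin2, a target of the pathway, 1.85-fold and Fzd8 1.47-fold lower; Wnt5a, 1.39-fold lower, was not called with the length slope. Of 29 cell cycle genes 15 fell and 4 rose (camera adjusted p = 0.124), and 6 and 3 fell with the covariates (7 and 5 adjusted over the list alone). Examples are Ccne2 at 2.27-fold, Kif11 at 1.87-fold, Ccna2 at 1.65-fold (not called with the length slope) and Top2a at 1.61-fold lower. Inflammatory mediators went both ways, 6 of 20 up and 7 down (camera adjusted p = 0.73), with C3 1.75-fold and Csf1 1.31-fold higher, and Ptgs2 2.34-fold and Tnfaip6 1.95-fold lower.

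The 10 largest rises among eligible genes included Angptl4, Aldh3a1, Nefh, Ddit4l, Mvd, Htra3, Cx3cl1, Dhcr7 and Akr1b8, and all passed with either covariate. The 10 largest falls were Inhba, Col4a3, Sema3d, Mstn, Atp7a, Spopl, Chrm2, Lrrc58, Nhs and Rest. Inhba, a subunit of activin, fell from 10.8 ± 6.75 to 0.752 ± 0.407 CPM (14.2-fold lower, or -3.83 on the log2 scale, against -1.70 and -1.21 with the covariates), and Mstn, myostatin, from 6.74 ± 0.904 to 0.942 ± 0.3 CPM. All 10 falls passed with the axis as a covariate, and 5 with the length slope, which left out Atp7a, Spopl, Lrrc58, Nhs and Rest.

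All 19 small ribosomal subunit genes rose, such as Rps3 at 1.53-fold (camera adjusted p = 3.7e-06, and adjusted p = 0.368 with an estimated correlation), against 11 with the axis (13 adjusted over the list alone) and 0 with the length slope as a covariate, where the list was no longer called (adjusted p = 0.142). Ribosomal protein genes held 2.296% ± 0.218 of the counts in control and 3.21% ± 0.324 in farnesol (SD, n = 5). Of 32 oxidative phosphorylation genes 23 rose (24 adjusted over the list alone) and 2 fell (camera adjusted p = 0.000431, and adjusted p = 0.382 with an estimated correlation), such as Cyc1 at 1.5-fold, and 0 passed with the length slope, where its call ended (adjusted p = 0.952). Of 26 lysosome and autophagy genes 16 rose and 5 fell, such as Sqstm1 at 1.46-fold (camera adjusted p = 0.0253, and adjusted p = 0.376 with an estimated correlation), a call that ended with the length slope (adjusted p = 0.292). Of 13 mitochondrially encoded messenger RNAs 2 rose (1 adjusted over the list alone), such as ND6, and 4 fell, such as ND4L (camera adjusted p = 0.939, median above and test below 0), and neither example passed with a covariate. With a length trend removed from each library this list was called lower, 8 falling (median log2 fold change -0.23, adjusted p = 0.0184, and adjusted p = 0.437 with an estimated correlation). ND6 lies opposite other mitochondrial genes and ribosomal proteins have many pseudogenes, so their counts are uncertain.

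**Figure D2:**
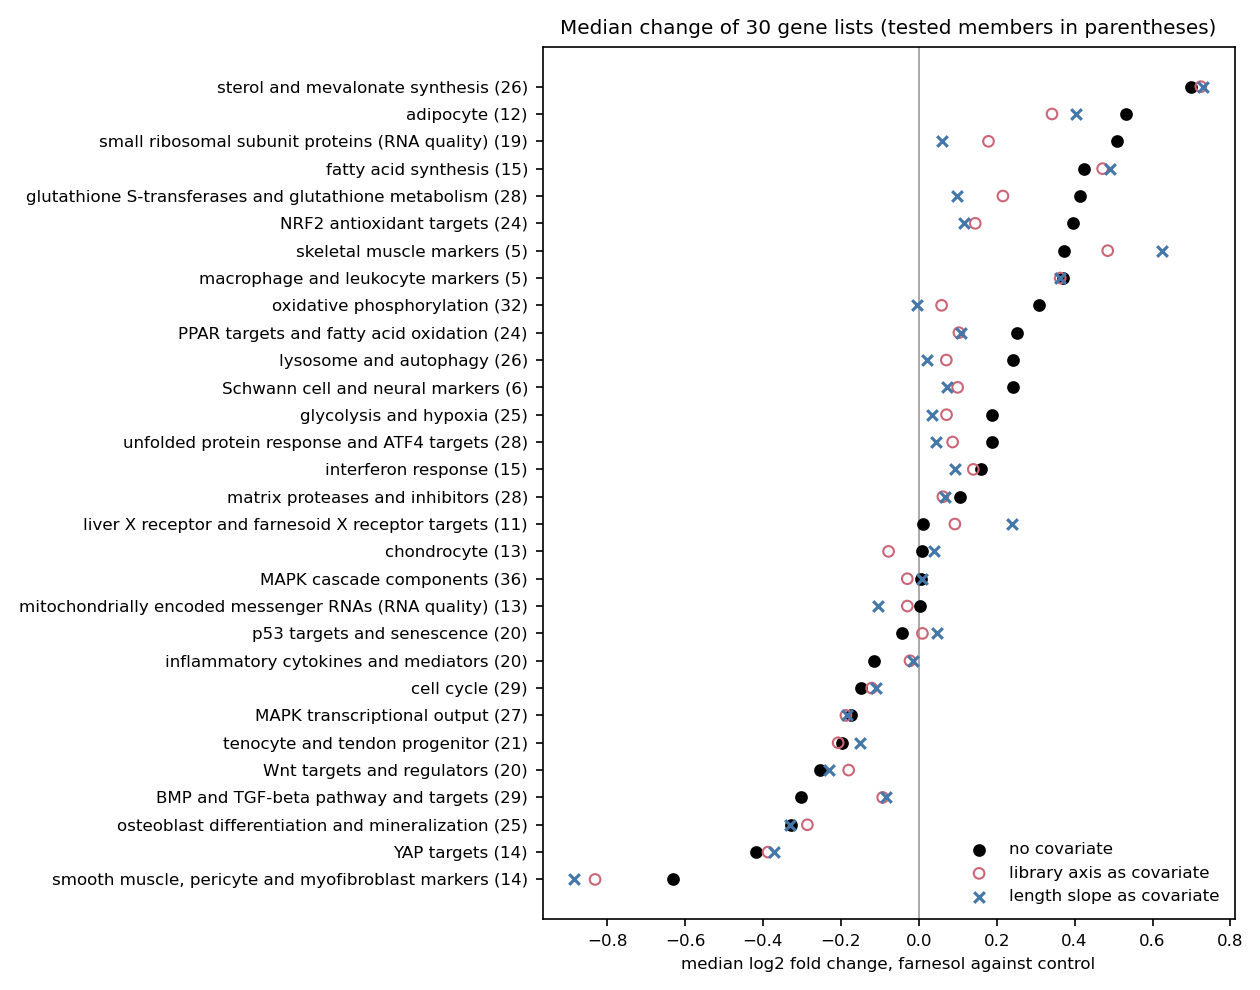
Median log2 fold change (horizontal axis, farnesol against control) of 30 gene lists, without a covariate (filled points), with the library axis (open points) and with the length slope (crosses) as a covariate. The sterol list stays near 0.7 and the smooth muscle list at or below -0.63, while the small ribosomal subunit list goes from 0.51 to 0.18 and 0.06.

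Library positions were uneven within groups. Scores on the axis were -40.3, -27, 4.06, -17.3 and -27.2 in control replicates 1 to 5 and 24.3, 11.8, -0.074, 11.8 and 59.9 in farnesol replicates 1 to 5, so that control 3 and farnesol 3 overlap. The first principal component held 62.1% of the variance and parted the groups (exact permutation test, 2-sided, p = 0.00794, the smallest this design can give). In 5245 genes, or 40.7% of those tested, the groups did not overlap, against 0.794% by chance.

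**Figure D3:**
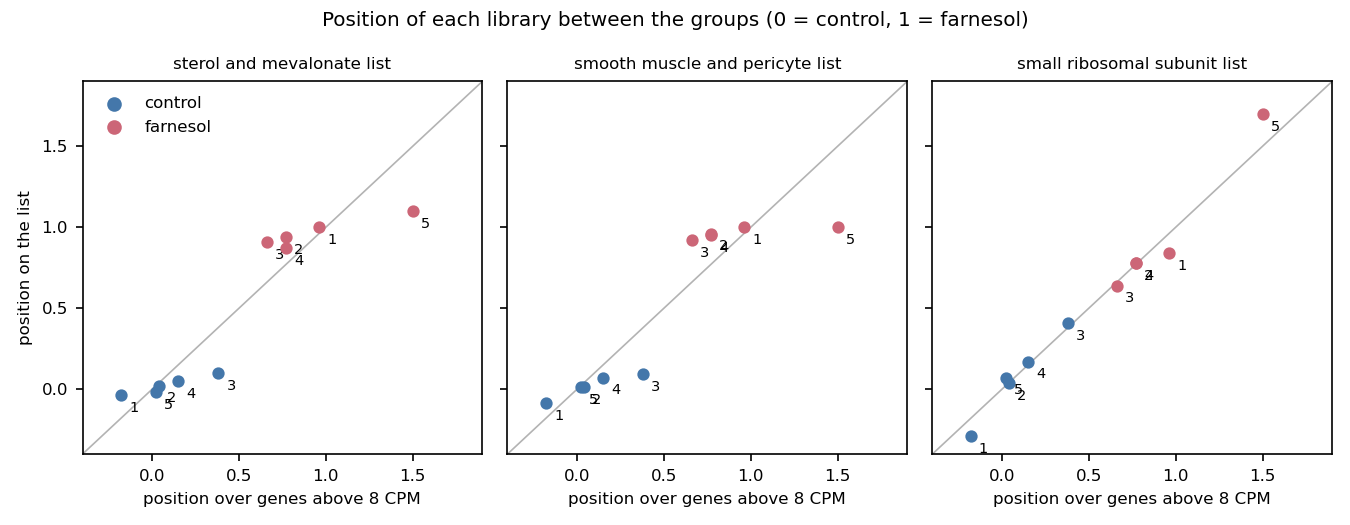
Position of each library between the groups, where 0 is the mean of the control and 1 that of the farnesol libraries, on the sterol, smooth muscle and small ribosomal subunit lists (vertical axes) against all genes above 8 CPM (horizontal axes); numbers are replicates and the line marks equal positions. Each mean leaves out the library itself and replicate 3 of both groups; control 3 lies at 0.38 over all genes and at 0.1 on the sterol list.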

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

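The tests of gene length on the fold changes, of library mixing, of the control libraries alone, of the axis and the length slope on each list and of the contractile markers were chosen only after the results were seen, while the counts over other splits and the test of ribosomal genes against matched genes were not. A library was looked at where its gap to the next one of its group was above 0.71 of the group's range, which chance reaches in about 1 in 20 groups, or 13.1 of the 262 groups looked at, against 15 found. Depth was compared first, only by the group means of 44.8 and 44.82 M counts, and was then replaced by the test of library mixing, so it was not tested further as a source of the fold changes.

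Of the 15, 7 were farnesol 5, which lay highest for Gstp1 at 412 CPM, Mvd at 51.9, Acaa2 at 37.3, Plin4 at 47.7, Ccnd1 at 768, Cspg4 at 222 and Sqstm1 at 638 CPM. Control 3 lay lowest for F3 at 462, Postn at 255 and Ccne2 at 13.7 CPM, and highest for Ddit4 at 12.6 and Sqstm1 at 408 CPM. Control 5 lay highest for Dcn at 24.1 and lowest for Plin4 at 19.1 CPM, and farnesol 4 highest for Fosb at 2.33 CPM. Farnesol 5 is also the far end of the library axis, at 59.9.

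Over 100 of the 126 splits of the libraries, only 1, the real one, called as many genes. This argues against chance alone as the source of the 7671 genes. Splits that mix the groups count the group difference as spread, and their median was 0 genes. Any difference between the groups would thus rank the real split first, so the count cannot tell farnesol from another such difference. The highest other count, 5940, came from the split that exchanges control 3 and farnesol 3, which points to a structure of these samples. For the gene lists 2 splits reached the real count of 14, with 15 in the highest other, and for the pathways 1 reached 51, with 49 in the highest other. Both are under 0.05 of the splits drawn, which argues against chance alone, although 1 other split called more lists than the real one. Not every split was drawn. Camera also called lists and pathways where 0 genes changed, such as 15 lists and 49 pathways in a split that exchanged 1 library. Splits that mixed the groups further called up to 7 lists and 19 pathways. Part of these counts can therefore arise without the real grouping.

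Fold changes followed the direction in which libraries of one group differ, with a correlation across genes of 0.696, genes not being independent replicates. Gene length as the whole source is argued against, since the correlation was 0.656 after the length trend was removed from every library. Exchange or mixing of libraries is argued against as well, since control 3 lay at 0.38 of the way to the farnesol libraries over genes above 8 CPM and at 0.1 on the sterol list, where mixing would give like positions. Farnesol as the only source is argued against by the control libraries, whose own main direction correlated at 0.586 with the fold changes. A state of the cultures or of the RNA that varies without farnesol and is shifted by it may account for the rest, and GC content was not tested.

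All 19 small ribosomal subunit genes rose, with a median log2 fold change of 0.509. Gene length alone is argued against, since the median was 0.298 and all 19 still passed with the length trend removed. Of 10000 random lists matched on length and expression, 100% had a lower median (0.28, middle 95% 0.097 to 0.42). The match was inexact (1342 against 1133 bp, and 297 against 393 CPM). Matched genes were also drawn independently, whereas the genes of the list moved together (estimated correlation 0.88). The range of the random lists is therefore too narrow, and this comparison cannot decide on length. With the axis as a covariate the median was 0.179 ± 0.0762 (SD over genes) and 11 passed; with the length slope it was 0.0589 ± 0.0873 and 0 passed, since the value itself shrank. A criterion of 2 SD over members, applied first, would have argued against the axis for this list; it was replaced, after that result, by the criterion used for the other lists, that over 0.5 of the median stays. The axis and a rise of ribosomal genes with farnesol cannot be told apart here, because farnesol libraries lie along it.

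As lists, the rise of sterol genes and the fall of contractile and YAP genes were not accounted for by the axis alone. The sterol median was 0.70 without a covariate, 0.724 with the axis and 0.73 with the length slope. This argues against either as the whole source of the list's rise. The contractile median was -0.63 and became -0.831 with the axis, and the YAP median -0.417 and -0.387, both still called. The YAP mean shrank from -0.568 to -0.46 with the axis, which may hold part of that fall. Single members went both ways with the axis. Mvd went from 1.35 to 0.709 and Insig1 from 1.04 to 1.26. Mylk went from -1.81 to -1.38 and Cnn1 from -1.01 to -1.23. A lower share of contractile cells in the farnesol cultures could lower the contractile markers, whose log2 fold changes spread with an SD of 0.689. Other cells of the culture may make some of them, so this and a change within cells cannot be told apart. A response of the cells to farnesol remains a hypothesis for both groups of genes.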

How the results depend on the processing

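Of 125 genes followed, 119 kept their direction and side of the threshold in every alternative not named here as chosen after seeing the data, and 85 in all alternatives. The exceptions to the former were Alpl, Map3k5 and Spp1, which lost their call in some, Col1a1 and Cspg4, which gained one, and Mapk14, which changed sign below the threshold. The alternatives with a covariate, with the length trend removed or without both end libraries were chosen after seeing the data. So were the library separation without single libraries and all pathway alternatives except camera with an estimated correlation and no covariate. Genes below about 1 CPM are limited by depth.

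Leaving out 1 library at a time gave 6880 to 7904 changed genes, 14 to 15 called lists, 51 to 55 pathways and 78.9% to 88% of the first component between groups. Over those fits the median log2 fold change ranged from -0.0483 to 0.259 for the chondrocyte (cartilage) list, from -0.0436 to 0.0478 for mitochondrial messenger RNAs, from -0.0603 to 0.0193 for the p53 list and from -0.00813 to 0.0219 for Mapk14, none called. Without control 1 and farnesol 5, 6794 genes changed.

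The replicate block gave 6409 genes and ended the calls of Alpl, Spp1 and Map3k5. After each group's mean was taken off, same-numbered libraries correlated at -0.07, 0.052, -0.4, -0.075 and -0.16, and none correlated best with its own number. These values show no pairing but cannot exclude it. The library axis holds 36.8% of the variance within groups and could hide a shared source, and the labels leave pairing open. With the block the cartilage median was 0.00297 and the p53 median -0.048, with tests of the other sign. With no filter the cartilage median was 0.282 and that of MAPK components 0.0382.

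The count of changed genes was 755 at an absolute log2 fold change of at least 1, since that adds a condition. It was 2656 with the axis and 976 with the length slope as covariates, and 7300 with the length trend removed. Camera with an estimated correlation called 2 lists and 0 pathways (41 and 10 pathways higher and lower with the preset), and fry, which compares no list with other genes, 24 and 244, with the p53 (-0.0421) and skeletal muscle (0.374) tests turned. With the axis and the length slope the adipocyte (adjusted p = 0.00737 and 0.00699), Wnt (0.0261 and 0.0437) and cell cycle (0.0037 and 0.00525) lists were called too, but not with an estimated correlation (adjusted p = 0.0515 and 0.0569, 0.0721 and 0.0981, and 0.0501 and 0.0696). With an estimated correlation 8 lists and 8 pathways were called with the axis, and 7 lists and 2 pathways with the length slope. With the length trend removed the bone and cell cycle lists (adjusted p = 0.0364 for each) and mitochondrial messenger RNAs (0.0184) were called, none with an estimated correlation, and the tendon (0.0909), unfolded protein response (0.131) and oxidative phosphorylation (0.114) lists, Runx2, Mapk8, Map3k5 and Abca1 were not. Without both end libraries the cell cycle list (0.0373) and Cspg4 (0.0132) were called and Map3k5 (0.0848) was not. Pathways numbered 31 with the length slope and 23 with the length trend removed. The causes were not tested.

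Signs turned as follows, none past the threshold except where said; for lists the median is given, and the sign that turned is that of the test. With the axis: Runx2 0.0189, Col1a1 -0.0309, Mapk14 -0.0369, Dusp6 0.0338, Abca1 0.0215, p53 list 0.00935 and skeletal muscle list 0.485. With the length slope: Runx2 0.119, Col1a1 -0.0523, Mapk8 0.0627, Mapk14 -0.0441, Map3k5 0.0842, Dusp6 0.0395, Col11a1 0.0504, Abca1 0.24, ND6 -0.0069, MAPK components 0.00823, p53 list 0.0457, oxidative phosphorylation -0.0048 and skeletal muscle list 0.624. With the length trend removed: Spp1 -0.00865, Cspg4 0.254, Ncam1 0.0361, liver X receptor targets 0.0696, MAPK components 0.124, matrix proteases 0.0269 and skeletal muscle list 0.406, and Pdgfrb at 0.197 was then called (adjusted p = 0.0294). Without both end libraries the p53 median was 0.0201.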

Other observations

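Camera with an estimated correlation and no covariate was planned for the pathways. The other pathway alternatives below were chosen after the results were seen. Of 330 KEGG pathways, camera called 51, with 41 higher and 10 lower, and with an estimated correlation 0, where 22 had an unadjusted p under 0.05; with an estimated correlation 8 were called with the axis and 2 with the length slope as a covariate, and fry without one called 244. Steroid biosynthesis (13 of 17 genes rose and 2 fell, adjusted p = 4.31e-05, and adjusted p = 0.197 with an estimated correlation), drug metabolism by cytochrome P450 (20 of 30 rose, or 22 adjusted over the list alone, and 0 fell, adjusted p = 4.31e-05, and adjusted p = 0.244 with an estimated correlation) and tyrosine metabolism (11 of 16 rose and 0 fell, adjusted p = 0.000485, and adjusted p = 0.279 with an estimated correlation) were higher and stayed called with either covariate. The cytoskeleton of muscle cells, with 76 of 177 genes lower and 25 higher, ECM-receptor interaction, with 28 of 62 lower and 9 higher, and focal adhesion, with 71 of 155 lower and 24 higher, were called as lower in all 3 fits (adjusted p = 0.0078, 0.0255 and 0.00635 in this order, and adjusted p = 0.552 for each with an estimated correlation). The ribosome pathway, with 114 of 148 genes higher (116 adjusted over the list alone) and 1 lower, was not called with the length slope (adjusted p = 0.515).

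Other fixed lists were not called by camera. Of 15 interferon genes 5 rose and 1 fell (adjusted p = 0.334), among them Usp18 at 1.84-fold and Stat2 at 1.36-fold higher, the latter not called with the length slope. Of 28 matrix proteases and inhibitors 11 rose and 11 fell (adjusted p = 0.873, mean below and test above 0), with Mmp3 1.44-fold higher and Loxl2 1.5-fold lower. Of 20 p53 and senescence genes 6 rose and 8 fell (adjusted p = 0.996, camera and fry of unlike sign), with Cdkn2b 1.91-fold higher and Fas 1.38-fold lower, the latter not called with the length slope. Of 25 glycolysis and hypoxia genes 11 rose and 5 fell (adjusted p = 0.124), with Adm 1.48-fold higher and Hif1a 1.9-fold lower, the latter not called with the length slope.

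Few markers of other cell types had enough counts to be tested, and some of those were well expressed. Which cells made them was not tested. Of 5 tested macrophage and leukocyte markers 2 rose, Cd14 from 49.9 ± 1.65 to 64.5 ± 1.53 CPM and Cd68 from 1.52 ± 0.54 to 3.05 ± 0.357 CPM (list adjusted p = 0.155, camera). Cd68 was not called with the length slope, where its log2 fold change was 0.94 (SE 0.4) against 1 (SE 0.23). Of 6 Schwann cell and neural markers 3 rose and 1 fell (adjusted p = 0.356). S100b was 1.53-fold higher (311 ± 19.7 and 477 ± 28.4 CPM). Ncam1 was 1.23-fold lower (498 ± 27.2 and 404 ± 4.9 CPM) and was not called with the length slope. Of 5 skeletal muscle markers 2 rose and 1 fell (adjusted p = 0.873, camera and fry of unlike sign). The latter, Acta1, was 2.17-fold lower (153 ± 10.9 and 70.5 ± 11.9 CPM). Endothelial markers and epithelial or synovial markers had 4 tested members each, at most 15 and 10.3 CPM, and blood markers 0.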
